A study of Danio rerio with 12 samples.

How the data were processed

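Zebrafish embryos and larvae of the AB strain were kept singly in wells for 7 days in control medium or in triclosan, an antibacterial agent used in consumer products, at 50 or 100 µg/L. Per the labels' protocols, larvae were pooled by 24, 6 pools were sampled per condition and 4 of them became libraries, which gives 12 libraries in 3 groups. DNA was studied by reduced representation bisulfite sequencing, in which the enzyme MspI cuts at CCGG sites and short fragments rich in CpG are sequenced after bisulfite conversion. Per the labels' protocols, fragments of 40 to 220 bp were selected and read once from one end for 100 bp. Replicates are separate pools from 1 experiment, and the labels do not say whether pools came from separate clutches.

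What could be analysed were 3 tables of the authors' own comparisons, 1 for each pair of groups, holding only the fragments the authors listed. Per the file headers, each deposited table gives a fragment's position, length and number of CpG sites, the methylation level of each group as a fraction, an F statistic with its degrees of freedom, an unadjusted p value, the number of libraries used in each group, an assigned gene and a CpG island. The build is Zv9, per the submitters' processing notes. The aligner, the methylation caller, the minimum coverage and the number of fragments tested are not given in the sources used here. Values per library and read coverage were not analysed here, so depth is unknown and no interval from read counts was made. Fractions are printed as percent, and differences as percentage points, second group minus first.

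Columns were read by position because the header of the table for 50 against 100 µg/L lies 1 column to the left of its values, after an extra column that holds a threshold per rank. That threshold equals rank times 0.05 over 184 tests, or 0.1 over 368, and the authors' false discovery rate is not known. With 184 tests, the largest adjusted p of the 99 fragments is 0.0984. Several properties of the tables were checked on all 171 entries, which cover 153 distinct fragments. The listed difference equalled the gap between both group levels within 0.01 points in 171 entries, and the degrees of freedom equalled the number of libraries minus 2 in 171. The deposited p value differed from the p recomputed from F by at most 0.126%. Every listed difference was at least 15 points. The gene distance was measured from the gene's start or end as marked, and in 41 of 69 entries inside a gene the marked end was the farther one, so it is called here the gene end the table measures from. The label for island shores was not used, since it was given to 85 entries lying 2.55 to 608 kb from the island. Of 149 distinct gene names, 120 were found in current zebrafish symbol tables, and names are printed as deposited.

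The standard error of a difference was computed as its size divided by the square root of the authors' F, and 95% intervals used the t distribution with the deposited degrees of freedom. This holds if F was computed on the same levels that the table prints. In 2000 simulated fragments per comparison, such intervals covered the true difference in 94.5%, 94.6% and 94.7% for control against 50, control against 100 and 50 against 100 µg/L. The simulated levels were normal with equal spread in both groups, as the interval assumes, so coverage near 95% checks the calculation only. The simulated fragments were also not selected by difference or p, so this coverage need not hold for the listed fragments. The planned tests per fragment need values per library, so none was run and the authors' p values are described. Fragments had been selected by the authors on these libraries, so their errors and p values are not independent evidence.

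Before the data were examined, the comparisons, 13 gene lists, the rule for naming genes and the alternatives were fixed. The rule takes the 10 largest rises and 10 largest falls per comparison with a gene name, every fragment listed more than once, every member of a gene list, and all fragments of a table of 20 or fewer. Directions were tested against an even split by a two-sided exact binomial test, adjusted by Benjamini-Hochberg over 3 comparisons. Median absolute differences were compared by a two-sided permutation test with 100000 resamples, adjusted over 3 pairs of lists. Locations were compared by Fisher's exact test, two-sided, adjusted over 18 tests. Fragments are the units of all these tests and are not independent replicates. Enrichment of gene lists was not tested, because no background of assayed genes was at hand.

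Lists that share a group share its chance values. Unchanged fragments were therefore simulated, 2000000 per setting with 4 control, 3 low-dose and 4 high-dose libraries and normal spreads of 6 to 20 points, and passed through the smallest difference and largest p of each deposited list. The setting whose listed fragments had the spread closest to the observed median is quoted, and others are named by their spread. The overlap of independent lists was not computed, as the number of fragments tested is not given, and groups could not be split without values per library. Alternatives were a p 10 times stricter, a difference of at least 20 points, merged fragments, numbered chromosomes, more CpG sites, other definitions of overlap, other statistics of size, windows of 2 and 10 kb, and gene assignment within 5 kb. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.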

Results

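Methylation of CpG-rich fragments was measured by reduced representation bisulfite sequencing in pools of 24 zebrafish larvae at 7 days post-fertilisation, with 4 libraries each for control, 50 µg/L and 100 µg/L triclosan. The design asked which fragments differ in methylation after developmental exposure to either concentration, and between both concentrations. The authors' deposited tables list 55 fragments for control against 50 µg/L, 17 for control against 100 µg/L and 99 for 50 against 100 µg/L, on build Zv9. All had differences of at least 15 percentage points. The largest unadjusted p was 0.0367, 0.0201 and 0.0530 in the same order, so the lists do not end at 1 common limit. Unchanged fragments, simulated as below with a spread of 8 points, were listed in 0.771%, 0.386% and 0.954%. The counts therefore do not show which dose changed more fragments. A fragment is named by its assigned gene, which is not evidence of a change at that gene: of 94 distinct fragments outside genes, 80 lay over 10 kb from the gene end the table measures from. Standard errors (SE) below are those implied by the tables' F statistics, and read depth is unknown.

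After 50 µg/L, adamts9, which encodes a secreted metalloprotease of the extracellular matrix, had the largest loss of methylation. In the authors' deposited table its intronic fragment (chromosome 11, 19601299 to 19601372) fell from 87.9% to 47.4%, with an SE of 9.79 points and 3 libraries in each group. The largest gain lay in an intron of kcnc3b, a voltage-gated potassium channel gene (chromosome 24, 38601692 to 38601904), which rose from 31.5% to 62.1% in the authors' deposited table (SE 4.58 points, 4 and 3 libraries). An exonic fragment of slc22a5, a carnitine transporter gene (chromosome 21, 44306319 to 44306389), fell from 56.6% to 30.6% (SE 4.72) in the authors' deposited table. Intronic nckipsd rose from 67.8% to 93.4% (SE 4.89), and a fragment 18.7 kb from plxnb2b, a semaphorin receptor gene, rose from 71.8% to 95.9% (SE 3.56), both per the authors' deposited table.

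Further falls at 50 µg/L in the authors' deposited table were 26.0 points at 9.26 kb from ppp1cc, a catalytic subunit of protein phosphatase 1 (SE 8.86), and 21.1 points in an intron of FRMPD2 (SE 7.26). Intronic sorl1, a sorting receptor gene, fell by 19.7 points (SE 6.45) and a fragment 16.1 kb from mgp, the gene of matrix Gla protein, fell by 19.6 points (SE 7.09) in the authors' deposited table. Both fragments on an exon of C1H11orf73 (chromosome 1, 577771 to 577849 and 577886 to 577942) rose in the authors' deposited table, by 15.1 (SE 4.73) and 20.4 points (SE 5.52). The fragment 2.21 kb from ora4, an olfactory receptor gene, lay inside a CpG island and rose from 23.3% to 41.4% (SE 4.31) in the authors' deposited table.

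Of the fragments at 50 µg/L assigned to symbols on the fixed gene lists, which do not hold every gene of a function, 5 were on the neuronal list, of which 4 rose and 1 fell. These were plxnb2b, neurod6a, a neuronal transcription factor gene (9.96% to 25.1%, SE 3.77), pcdh17 (27.7 kb away, 78.2% to 95.6%, SE 2.75) and dlgap4a upwards, and PCDH9 downwards (257 kb away, 45.7% to 28.2%, SE 3.14), in the authors' deposited table. Of 4 fragments on the heat shock list, 3 fell and 1 rose. The fragment assigned to hspb1, a small heat shock protein gene, lay 114.5 kb from it and fell by 19.6 points (SE 6.62) in the authors' deposited table. Fragments 249 kb from dnajc19 and 73.3 kb from dnajc24 fell by 15.8 (SE 5.05) and 15.1 points (SE 5.01), and one 14.01 kb from dnajc9 rose by 15.2 (SE 5.17), in the authors' deposited table. Of the 7 entries on the heat shock list over all comparisons, 0 lay in a gene or within 5 kb. Of 4 fragments on the transcription factor list, that assigned to irx1a, 56.1 kb away, rose by 20.4 points (SE 6.29) in the authors' deposited table. Those assigned to irx2a (114.3 kb away), runx1t1 (3.22 kb away) and the cardiac factor gene gata4 (on an exon) fell. The adhesion and matrix list held 5 fragments, with itgb1b and pcdh17 higher and cdh7, PCDH9 and adamts9 lower, and does not count mgp. Intronic fragments of the growth factor gene gdf5 fell by 19.7 points (SE 5.96) and tnfrsf21, a death receptor gene, by 16.4 (SE 3.15) in the authors' deposited table.

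In all, 23 of the 55 fragments rose and 32 fell at 50 µg/L, which did not differ from an even split (41.8% higher, 95% interval 28.7% to 55.9%, two-sided exact binomial p = 0.281, adjusted p = 0.421). The authors' deposited table gives unadjusted p values of 0.00106 to 0.0367, and only 3 of the 4 low-dose libraries were used for 46 of the 55 fragments.

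After 100 µg/L, both listed fragments assigned to znf536, a zinc finger gene expressed in brain, gained methylation. In the authors' deposited table one, 97.3 kb from the gene (chromosome 7, 47883469 to 47883615), rose from 39.9% to 63.3% (SE 6.44, 3 and 4 libraries) and the other, 24.4 kb away (47956467 to 47956541), from 51.0% to 66.6% (SE 2.14, 4 and 4 libraries). The largest falls were at hapln3, a hyaluronan and proteoglycan link protein gene, whose exonic fragment (chromosome 25, 19692813 to 19692858) dropped from 77.3% to 56.5% (SE 5.70) in the authors' deposited table, and 14.3 kb from DNAJC30 (2 of 2), from 61.0% to 40.6% (SE 3.82). Fragments 32.4 kb from nfe2l1a, a stress-response transcription factor gene, and 5.68 kb from zmiz1a fell by 19.7 (SE 4.47) and 19.1 points (SE 5.96) in the authors' deposited table. The intronic fragment of CABZ01114082.1 rose by 19.04 points (SE 3.90) and that of dhodh, an enzyme of pyrimidine synthesis, by 16.1 (SE 3.32) in the authors' deposited table.

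The neuronal list held 2 fragments in this comparison, both higher at 100 µg/L. Fragments 138 kb from the synaptic adhesion gene nlgn1 and 14.98 kb from the postsynaptic scaffold gene dlgap4a rose by 15.1 (SE 3.54) and 16.1 points (SE 4.05) in the authors' deposited table. An intronic fragment of the calcium channel subunit gene cacna2d2 fell by 16.4 points (SE 4.23), and intronic fragments of ptprk, TRIM67 and casz1 fell by 16.8, 17.2 and 15.6 points, in the authors' deposited table. Of the 17 fragments 8 rose and 9 fell (47.1% higher, 95% interval 23.0% to 72.2%, two-sided exact binomial p = 1). The authors' deposited table gives unadjusted p values from 0.000331 to 0.0201 here and no threshold column.

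Between 50 and 100 µg/L, uqcrc2a, which encodes a core subunit of respiratory complex III, had the largest difference. Its intronic fragment (chromosome 3, 59042926 to 59043000) fell from 53.7% to 14.4% (SE 6.40, 3 and 4 libraries) in the authors' deposited table. Falls followed at 35.97 kb from zbtb43 (90.9% to 62.7%, SE 4.95), 18.7 kb from plxnb2b (95.9% to 69.9%, SE 4.72) and 145 kb from tmem55a (62.9% to 38.4%, SE 7.30) in the authors' deposited table. The exonic hapln3 fragment fell from 80.9% to 56.5% (SE 3.14), and one 12.01 kb from F2RL2 (1 of 2), a protease-activated receptor gene, from 81.0% to 57.3% (SE 2.72), in the authors' deposited table. The largest rises were intronic adamts9 (47.4% to 80.6%, SE 9.77, 3 libraries each), intronic erc1b, an active-zone scaffold gene (50.4% to 76.3%, SE 9.25), and a fragment 71.3 kb from CCBL2 (3 of 4) (57.2% to 82.3%, SE 3.69), in the authors' deposited table. Intronic atp8b5a, a phospholipid flippase gene, rose from 68.9% to 92.3% (SE 2.15), exonic wasf3, an actin regulator gene, from 45.4% to 68.3% (SE 7.27), and intronic lrp1b from 66.1% to 87.4% (SE 2.76), in the authors' deposited table. Of these, adamts9, erc1b, wasf3 and tmem55a had p above the threshold per rank in that table. Its level is uncertain, since it equals 0.1 times rank over 368 tests or 0.05 times rank over proportionally fewer, and the table does not say which.

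The fixed lists held mixed directions here. Of 4 transcription factor list members, dlx6a (35.6 kb away) fell by 22.3 points (SE 8.24) and lhx2b (102 kb away) by 16.2 (SE 5.39), whereas nkx3.2 (27.6 kb away) rose from 69.3% to 84.3% (SE 4.11) and GATAD2B (153 kb away) by 17.7 points (SE 5.54), in the authors' deposited table. GATAD2B is a subunit of a chromatin remodelling complex rather than a GATA factor. Both fragments on the neuronal list, which does not hold erc1b, fell (plxnb2b and neurod6a), and both on the heat shock list, hspb1 and dnajc19, rose. A fragment 28.9 kb from the Wnt receptor gene fzd4 was 17.9 points higher (SE 5.50) and an intronic one of smad6b, an inhibitor of BMP signalling, rose by 15.4 (SE 2.91) in the authors' deposited table. The single member of the chromatin list, an intronic fragment of setd3, whose protein methylates actin, was 15.5 points higher (SE 5.39) in the authors' deposited table. The adhesion and matrix list, which does not hold hapln3, had 4 fragments, with adamts9, CDH12 (1 of 2) and COL28A1 (4 of 4) higher and CDHR2 (2 of 2) lower at 100 µg/L. Of the cation channel copies, TRPC7 (3 of 4), 10.06 kb away, rose by 16.9 points (SE 2.96), and TRPC7 (1 of 4), 154 kb away, was 15.5 points higher with an interval of −0.128 to 31.0, from the authors' deposited table. Of all these list members, only plxnb2b, neurod6a, hspb1, dnajc19, smad6b, COL28A1 (4 of 4) and TRPC7 (3 of 4) had p at or under the threshold per rank. No symbol on the fixed lists for xenobiotic metabolism, thyroid, steroid, lipid and muscle genes, 5 of the 13 lists, was assigned a fragment in these tables. Genes of such functions outside those lists, such as slc22a5, are not counted, and there was no background to test the 0 against.

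In this comparison 64 of 99 fragments rose from 50 to 100 µg/L and 35 fell (64.6% higher, 95% interval 54.4% to 74.0%, two-sided exact binomial p = 0.00464, adjusted p = 0.0139). As in the other comparisons, the fragments share the same few pools, so the interval and p values do not measure the spread between pools. Rises were 10 of 23 among differences of at least 20 points and 18 of 33 among the fragments whose p lay at or under the threshold per rank in the authors' deposited table (exact binomial p = 0.678 and 0.728). Rising fragments averaged 116 bp and falling ones 85.1 bp, and only 3 of the 4 low-dose libraries were used for 87 of the 99.

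**Figure D1:**
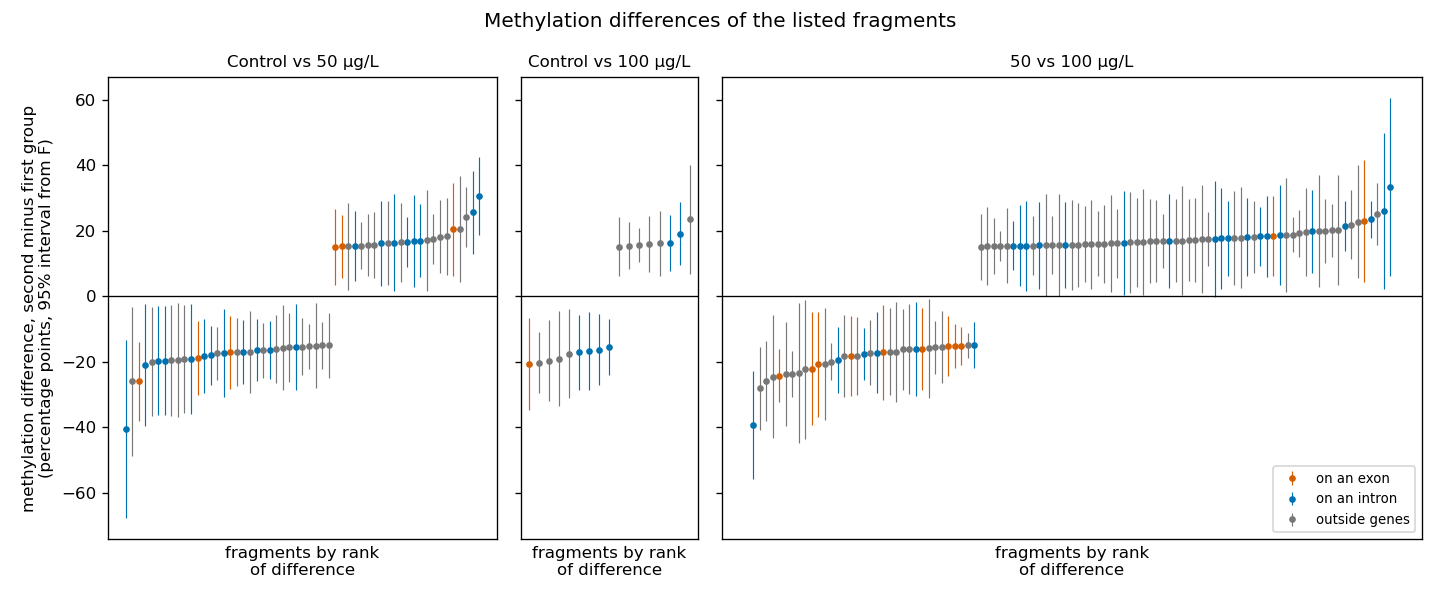
Methylation difference of each listed fragment in percentage points (vertical axis, second minus first group) against its rank (horizontal axis), for the 3 comparisons. Points are coloured by location, bars are 95% intervals implied by F, and 3 of the 99 intervals for 50 against 100 µg/L include 0.

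Fragments listed in more than 1 comparison let all 3 group levels be compared. For 15 fragments listed both for control against 50 µg/L and for 50 against 100 µg/L, 50 µg/L lies at least 15 points from both other groups by selection. The level of adamts9 was 87.9% in control, 47.4% at 50 and 80.6% at 100 µg/L in the authors' deposited tables, and that of neurod6a was 9.96%, 25.1% and 9.86%. In the same order, hspb1 had 56.8%, 37.2% and 52.6%, and cybb, the gene of a phagocyte oxidase subunit, 79.4%, 95.7% and 78.5%, in the authors' deposited tables. Of these 15, 8 were lowest and 7 highest at 50 µg/L, and the gap between control and 100 µg/L was 0.100 to 8.03 points (median 1.83). Unchanged groups, simulated as below with a spread of 8 points and listed in both comparisons, had opposite signs in 100%. Their median gap was 1.79 points, and it was 1.24 and 2.78 points at spreads of 6 and 10. No gap between control and 100 µg/L could be told from 0 by the widest 95% interval that both F statistics allow, although 4 of the 15 gaps exceeded the largest SE they allow. In the table for 50 against 100 µg/L, 6 of the 15 had p above the threshold per rank, among them adamts9, cybb and slc22a5. At dlgap4a, the 1 fragment listed for both doses against control, levels were 49.8%, 65.3% and 65.9% in the authors' deposited tables. Both CABZ01114082.1 (58.4%, 57.7%, 77.5%) and hapln3 (77.3%, 80.9%, 56.5%) were listed for 100 µg/L against control and against 50 µg/L in the authors' deposited tables.

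The 15 shared fragments were 27.3% of the 55, against 13.1% when unchanged groups sharing the 50 µg/L pools were simulated. For both doses against the shared control, 1 fragment, or 1.82% of the 55, was shared (95% interval 0.0460% to 9.72%). The simulated share was 4.70%, which lies inside that interval. This share and the 13.1% were simulated with a spread of 8 points. For the pair sharing 100 µg/L, 11.8% of the 17 (95% interval 1.46% to 36.4%) were shared against 9.76% simulated at 8 points and 5.52% at 6, the spread closest to that list. Part of each overlap may come from the shared pools, which could not be split.

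**Figure D2:**
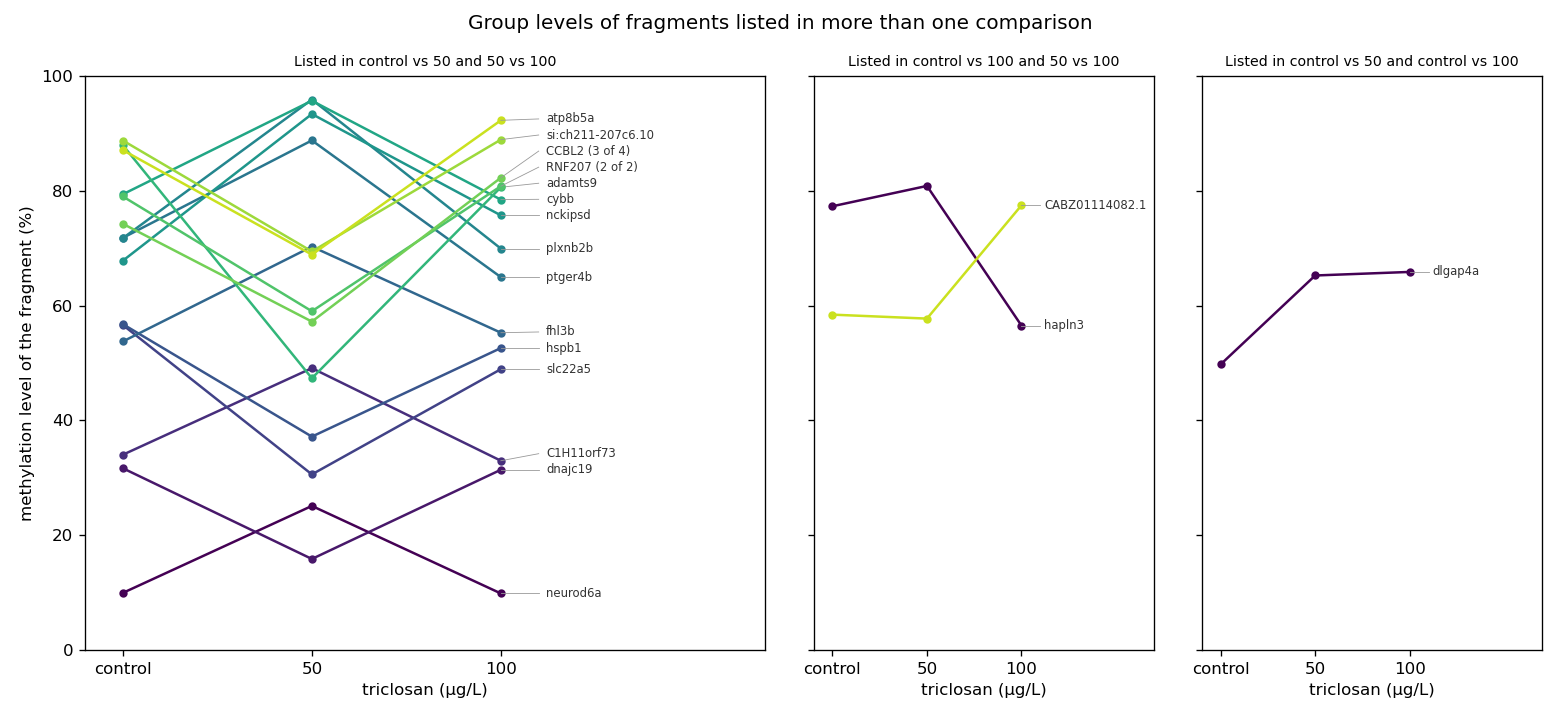
Methylation level in percent (vertical axis) in control, 50 and 100 µg/L triclosan (horizontal axis) for the 18 fragments listed in more than 1 comparison, 1 line per fragment with its assigned gene. The tables give no error per group; the 15 fragments on the left are lowest or highest at 50 µg/L.

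Listed differences had similar sizes, with median absolute differences of 17.03, 16.76 and 17.23 points for control against 50, control against 100 and 50 against 100 µg/L. No difference was detected in the 3 pairs (two-sided permutation test, adjusted p = 0.790 for each), and all lists share a lower limit of 15 points. Of 153 distinct fragments, 14 lay on an exon, 45 on an intron and 94 outside genes, at a median of 51.8 kb from the gene end the table measures from. Only 7 lay outside a gene but within 5 kb of it, and 4 lay inside a CpG island, assigned to ppp1cc, dnajc9, ora4 and CABZ01112647.1.

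Among the fragments listed for 50 against 100 µg/L, location differed by direction. These fragments share the same few pools, so the p values here do not measure the spread between pools or show a dose effect. Of 21 rising fragments inside genes, 2 lay on an exon and 19 on an intron, and of 15 falling ones, 9 lay on an exon and 6 on an intron (two-sided Fisher's exact p = 0.00244, adjusted p = 0.0440 over 18 tests). Exonic falls included hapln3, neurod6a, gal3st1 and C1H11orf73, whereas wasf3 and slc22a5 were the 2 exonic rises. Exonic fragments were shorter, with a median of 74 bp against 97 bp on introns, and p was 0.00568 with directions permuted within length classes. In each class alone Fisher's exact p was 0.0669 (100 bp or shorter) and 0.0813 (over 100 bp), with rises rarer on exons in both. At or under the threshold per rank, 0 of 4 exonic and 4 of 8 intronic fragments rose (Fisher's exact p = 0.208), over 12 fragments in place of 36. The other location tests of the 18 had adjusted p = 1 (Fisher's exact).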

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

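The comparisons and the overlap of lists were planned, and the tests of explanations in this part were chosen after the patterns had been seen.

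At 15 fragments listed for 50 µg/L against control, a difference between both doses was also listed, and all 15 lay closer to control at the higher dose. Being listed in both comparisons is how these fragments were chosen, so the F test between both doses is not separate evidence that the responses differed. Opposite signs were also found in 100% of unchanged simulated fragments listed in both comparisons. Of the 15, 6 (C1H11orf73, ptger4b, si:ch211-207c6.10, adamts9, cybb and slc22a5) had p above the authors' threshold per rank between both doses, as had CABZ01114082.1. At 2 further fragments, CABZ01114082.1 and hapln3, chosen by being listed for 100 µg/L against both other groups, the level at 50 µg/L was near control.

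The 15 fragments include adamts9, plxnb2b, slc22a5, neurod6a and hspb1. A missing library at 50 µg/L cannot account for 4 of them (C1H11orf73, si:ch211-207c6.10, dnajc19 and neurod6a), which used all 4 low-dose libraries. The other 11 were measured in 3 low-dose libraries, and for them a missing library stays open. Of the fragments listed for control against 50 µg/L, 4 of 9 with all 4 low-dose libraries were shared, and 11 of 46 with 3 (Fisher's exact p = 0.236). For all 15, deviating libraries among those used cannot be told apart from a dose effect without values per library. Chance values of the shared 50 µg/L pools may also contribute, because unchanged simulated groups listed 13.1% of fragments again, with opposite signs. The observed share was 27.3% (95% exact binomial interval 16.1% to 41.0%). For a spread of 10 points the simulated share rose to 17.7%, inside that interval, so this stays open. The simulated median gap between control and 100 µg/L followed the assumed spread, with 1.24, 1.79 and 2.78 points at spreads of 6, 8 and 10. Its closeness to the observed 1.83 at a spread of 8 is therefore not evidence for chance. A response that peaks at the lower dose is a biological hypothesis that these tables leave untested.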

How the results depend on the processing

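Restricting to all 4 libraries, to the threshold per rank, to unshared fragments or to length classes was chosen after seeing the data; other alternatives were planned. No paired analysis was possible because the tables hold no values per library; for the same reason leaving out each library, the coverage minimum of reads and other tests per fragment were not run, and depth limits could not be judged. Counts of listed fragments fell from 55, 17 and 99 (control against 50, control against 100, 50 against 100 µg/L) to 9, 3 and 27 at a p 10 times stricter, to 9, 3 and 23 at 20 points or more, to 21, 8 and 47 with more CpG sites than the median, and to 4, 9 and 12 with all 4 libraries of both groups; 33 of the 99 lay at or under the threshold per rank. A stricter rule leaves fewer fragments by construction, and merging left 98 of the 99. With all 4 libraries, however, the order of control against 50 and control against 100 µg/L turned. Only 3 dose libraries were used for 46 of the 55 fragments at 50 µg/L, and for 1 of the 17 at 100 µg/L.

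The share of rises for 50 against 100 µg/L, 64.6%, was no longer called at a stricter p (51.9%), with all 4 libraries (75.0%) or at or under the threshold per rank (54.5%), and turned at 20 points or more (43.5%); the cause was not tested. It stayed called with 1 direction per gene (63.5%) and without shared fragments (67.1%). The uncalled shares turned to 55.6% for control against 50 µg/L at a stricter p and to 55.6% at 20 points or more, and to 66.7% for control against 100 µg/L at a stricter p. On the log2 ratio, the uncalled differences of median size turned to −0.0280 (control against 50 minus control against 100) and 0.0221 (control against 100 minus 50 against 100). The Fisher's exact p for exons against introns was 0.208 at or under the threshold per rank, where the call was lost with 12 fragments in place of 36 and intronic rises in 4 of 8 in place of 19 of 25 (exonic 0 of 4 in place of 2 of 11), and 0.00223 without shared fragments. Windows of 2 and 10 kb held 4 and 15 entries in place of 7, and the 15 count ptger4b both for control against 50 and for 50 against 100 µg/L. Members of gene lists went from 34 to 11 when only fragments in a gene or within 5 kb counted. Overlaps between lists stayed at 1, 15 or 16, and 2 under other definitions. Of 94 named entries, 26 passed the stricter p and 32 reached 20 points.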

Other observations

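All tests in this part were chosen after their values were seen.

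Genes with 2 listed fragments in 1 comparison (C1H11orf73, znf536, erc1b and si:ch211-207c6.10) had both moving the same way. Over all pairs of listed fragments within 100 kb of each other, 5 of 6 moved the same way, which did not differ from an even split (two-sided exact binomial p = 0.219), and the exception was irx2a and irx1a at 50 µg/L. The second erc1b fragment, in an intron, rose from 49.0% to 67.2% (SE 3.52) between 50 and 100 µg/L, and the second si:ch211-207c6.10 fragment, 56.2 kb from the gene, from 77.7% to 93.0% (SE 1.73), in the authors' deposited table.

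Chromosome 5 held 15 of the 99 fragments for 50 against 100 µg/L, including hspb1, zbtb43, gal3st1 and atp8b5a. Its share of chromosome length, taken from the largest coordinates, is 6.25%. The excess of fragments did not pass a correction for 25 chromosomes and 3 lists (one-sided exact binomial p = 0.00124, p = 0.0931 after multiplying by 75).

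Between 50 and 100 µg/L the 64 rising fragments averaged 116 bp and the 35 falling ones 85.1 bp (two-sided permutation p = 4e-05, adjusted p = 0.00024 over 12 tests of length, CpG number and both levels in 3 comparisons). Adjusted over the 3 tests of length alone, permutation p was 0.00012. Fragments are the units here and share the same few pools, so these p values do not measure the spread between pools or show a dose effect. For control against 50 µg/L the means were 93.0 and 91.8 bp (permutation p = 0.910). For control against 100 µg/L they were 115.6 and 80.3 bp, a difference of 35.3 bp in the same direction (exact permutation p = 0.0661), and differences between comparisons were not tested. Exon or intron location as the whole cause is argued against by fragments outside genes, where rising ones were also longer (permutation p = 0.00262). The difference also stayed with directions permuted within classes of mean level (permutation p = 2.0e-05). That covers only the mean of both groups. The level at 50 µg/L averaged 53.3% in rising and 67.9% in falling fragments and was not held fixed, so methylation level stays open. A candidate explanation that stays open is reads running through fragments of 100 bp or less into bases filled in at their ends. Whether such reads differed between both doses was not tested. Above 100 bp the length difference was 8.24 bp (permutation p = 0.190, 95% bootstrap interval −1.97 to 18.8), and at or below it 14.6 bp (permutation p = 0.00184). The interval above 100 bp includes 14.6 bp, so this test could not tell both length classes apart. The rule for this last test was rewritten after its values were seen, because such reads would give a gradient among short fragments too, and size selection that differed between groups was not tested.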
